A study of Homo sapiens with 92 samples.

How the data were processed

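Messenger RNA was measured in human whole blood that had been irradiated outside the body. Blood of 12 donors was divided into aliquots, and each aliquot received 1 dose of X-rays or of neutrons, or was sham irradiated as the control. RNA was taken 24 h later and hybridized, 1 sample per array, to 92 Agilent 1-colour (Cy3) oligonucleotide arrays. The work had 2 parts with 6 donors each, the second at lower doses. The array files carry a slide identity, which placed the arrays on 25 slides of up to 4 arrays each.

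The deposited file of each array holds fluorescence intensity per spot, made by the authors with Agilent Feature Extraction. Per the file headers the software version was 11.5.1.1 in the first part and 12.0.2.2 in the second, whereas the submitters' processing notes give 10.7. The processed signal in these files is background-subtracted and detrended within the array and is not normalized between arrays. The deposited series matrix holds log2 values of the same signals for 12289 probes. Of these, 11841 matched a probe used here, and 100% of the matched values equalled the log2 processed signal plus 1 constant per array, within a tolerance of 0.005. In that matrix 4.2% of the values were missing and the array medians lay between 5.11 and 6.73. The file headers give probe positions on the hg19 build, and no genome sequence was used.

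The processed signal of each probe was averaged over its repeated spots on the log2 scale, and the array's 75th percentile was subtracted. Control spots and spots that the software had marked as non-uniform or as outliers among repeats were left out. Probes were named by their RefSeq accession (26449 probes), by a current symbol (2114) or by an older symbol (358), 3242 kept the name in the file, and 1964 had no gene name and were left out of the tests by gene. XIST and Y-linked genes were left out of all results. A probe was kept when it was well above background on at least 75% of the arrays of at least 1 group and missing on at most 10% of the arrays. The brightest kept probe stood for its gene, which gave 17714 genes, 821 of them with at least 1 missing value.

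Genes were compared with limma 3.58.1 in R 4.3.3 (the files were read with data.table, version 1.17.8), in 1 fit of all 92 arrays with the 12 groups and the donor as a fixed block, because aliquots of 1 donor were paired. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold for the adjusted p. Each log2 change is given with its moderated standard error (SE). Dose slopes were fitted in the second part, with donor as a block, as straight lines in log2 per Gy. A further fit asked whether responses to the 3 exposures used in both parts differed between the parts. A fold is called "at least" when the probe was not well above background on any array of 1 group. The values of that group below the lowest signal that was well above background on the same array were raised to that signal, so the fold is a lower bound. A log2 change printed beside such a fold is the fitted change of the probe's signal and not a measured size, for which only the bound holds.

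The genes named follow a fixed rule: in each of 4 main comparisons the 12 genes with the highest and the 12 with the lowest log2 change among those past the threshold that moved the same way in every donor, a fixed panel of 20 radiation-response genes, and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be so. The 26 gene lists were written from general knowledge, not from these data, and 18 comparisons were tested on each. Their genes were tested as sets with limma's camera at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a set moves on balance 1 way without comparing it with other genes. Adjusted p-values of lists are over the 26 lists. Camera p-values at the preset correlation are small because they take the genes of a list to be nearly independent, so the value with an estimated correlation is given beside them.

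For each list a score per array was the mean over the list of each gene's log2 signal minus that gene's mean over all arrays. Scores were compared between aliquots of the same donor by exact two-sided sign-flip permutation tests, with p-values adjusted over the 18 comparisons of a list. With 11 donors the smallest p that such a test can give is 0.000977, with 6 donors 0.0312, with 5 donors 0.0625 and with 4 donors 0.125, so comparisons of 5 donors or fewer cannot pass 0.05. The X-ray dose that matches a neutron dose on a score was read by straight lines between the X-ray groups, and its SE came from leaving out 1 donor at a time. Overlap of the 1 Gy results was set against 50 simulations in which both exposures shared their controls and no gene changed. It was also set against fits of each exposure in a different part, where donors, irradiated arrays and controls all differed.

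The signal at the 75th percentile ranged from 81.8 to 1551 intensity units in the first part (median 824) and from 70.9 to 1326 in the second (median 902). Between 48.6% and 88% of the probes were well above background on an array. The coefficient of variation (CV) of repeated probes lay between 3.49% and 14.4%. The number of arrays limits the precision of the results. In 4 arrays the signal was under 400 units, and in 3 others the repeated probes varied by over 8%. These 7 are called the low quality arrays.

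Donor labels were checked through residual profiles: pairs of arrays of 1 donor correlated with a mean r of 0.567 over 313 pairs, and arrays of different donors in the same part with a mean r of -0.085. No array pair held identical values (0 pairs). These correlations are across genes, which are not independent replicates. In the first part each slide held arrays of 1 donor only, so slide and scan day also enter the r within donors. The labels were therefore not checked apart from these. Profiles were centred on the group mean, which by itself lowers r between different donors. In data simulated from these arrays with 200 genes changed, a change of 1 on the log2 scale was recovered for 87% of genes at 1 Gy neutron, 86% at 1 Gy X-ray, 76% at 4 Gy X-ray and 90% between the radiations. For a change of 0.5 the shares were 55%, 55%, 42% and 51%. False calls made up 1.4%, 7.2%, 2.5% and 6% of the genes called. The list test found the 1 list that was shifted and called 0 others. The simulated noise was independent between genes and between arrays, with no slide effect and no correlation within a list. These rates therefore hold for such data and are not the error rates of the real arrays.

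The samples' grouping, the comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were quantile normalization, scaling to the array median, a normexp background with an offset of 50, no filter or a stricter filter on dim probes, the mean of all kept probes of a gene, the series matrix values, no donor block, donor or slide as a random block, each part alone, fits of only the groups compared, each donor left out in turn, both parts up to 1 Gy for the slopes, the median of a list's genes and the square root of dose. Leaving out the 7 low quality arrays and fitting slide as a fixed block were added after the data had been seen.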

Results

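Blood of 12 donors was profiled after X-rays or neutrons, 6 donors in each of 2 parts. The first part had 6 arrays each for the control, for neutron doses of 0.25, 0.5 and 1 Gy and for X-ray doses of 1, 2 and 4 Gy. The second part had 6 arrays each for neutron doses of 0.3 and 1 Gy and for X-ray doses of 0.1, 0.3 and 0.5 Gy, and 5 each for the control, 0.1 Gy neutron, 0.5 Gy neutron and 1 Gy X-ray. Pooled over the parts there were 11 controls, 11 arrays of 0.5 Gy neutron, 12 of 1 Gy neutron and 11 of 1 Gy X-ray. The first part had 42 arrays with a median signal of 824 intensity units at the 75th percentile, and the second had 50 with a median of 902. In the first part 3 arrays had a signal under 400 units and 3 had repeated probes that varied by over 8%, and in the second part 1 and 0 arrays did. A median of 71% of the probes in the first part and 73.7% in the second were well above background.

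The first question was which genes 1 Gy of neutrons changed. Targets of p53, the transcription factor that DNA damage activates, rose most. The probe of EDA2R, a member of the TNF receptor family, rose by 6.27 ± 0.17 on the log2 scale (SE, 11 donors, adjusted p = 3.85e-44; X, 65815490 to 65815549). This was at least 28.1-fold, because 0 of 11 control arrays were well above background. FDXR, a mitochondrial electron carrier, rose 14.7-fold (3.88 ± 0.11, adjusted p = 1.03e-43; chromosome 17, 72858650 to 72858709). APOBEC3H, a cytidine deaminase, rose 15.2-fold (3.93 ± 0.11, adjusted p = 4.19e-44; chromosome 22, 39497974 to 39498033). TCL1A, a kinase coactivator of naive B cells, fell by 1.82 ± 0.13 (adjusted p = 2.01e-20; chromosome 14, 96176290 to 96176337). These 4 moved the same way in 11 of 11 donors. VPREB1, part of the surrogate light chain of B cell precursors (chromosome 22, 22599858 to 22599917), was lower, but no size is given. It was well above background on 9 of 11 control arrays but on 1 of 12 irradiated arrays.

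All 20 genes of the fixed panel rose. Among them DDB2, which recognises ultraviolet lesions, rose 6.91-fold (2.79 ± 0.07, adjusted p = 1.01e-46; chromosome 11, 47260623 to 47260682). GADD45A, a growth arrest gene, rose 5.5-fold (2.46 ± 0.06, adjusted p = 5.07e-49; chromosome 1, 68153371 to 68153430). AEN, an apoptosis nuclease, rose by 3.30 ± 0.28 (chromosome 15, 89174900 to 89174959), and CD70, a ligand of the TNF family, by 2.87 ± 0.11 (chromosome 19, 6585867 to 6585926). CDKN1A, the p21 cell cycle inhibitor, rose by 2.35 ± 0.24 (10 of 11 donors; chromosome 6, 36652178 to 36652237) and MDM2, the ubiquitin ligase that limits p53, by 2.11 ± 0.10 (chromosome 12, 69238891 to 69238950). The other panel genes ranged from SESN1, a metabolic stress gene (1.48), and XPC, a repair gene (1.44 ± 0.12), to TNFSF4, a T cell costimulator (3.02 ± 0.17). Also among the 12 highest were UNC5B-AS1, an antisense transcript (at least 4.14-fold), and SPATA18, a mitochondrial quality gene (at least 3.29-fold, measured well above background on 11 of 12 irradiated arrays). VWCE rose 14.7-fold, PAPPA, a metalloprotease, rose 12.3-fold (well above background on 7 of 11 control arrays), and E2F7, a transcriptional repressor, rose 10.2-fold (5 of 11 control arrays). HRK, an apoptosis activator, fell by 2.29 ± 0.17 (adjusted p = 1.12e-18; chromosome 12, 117299053 to 117299112). Genes that also fell in every donor included DOK7, a kinase adaptor (-1.73 ± 0.19), PRICKLE1, a planar polarity gene (-1.55 ± 0.18), SELENOP, a selenium carrier (-1.37 ± 0.27), PACSIN1 (-1.32 ± 0.10) and the lipid transporter ABCB4 (-1.27 ± 0.13). ZMAT4 (no size is given, 2 of 12 irradiated arrays well above background) and PCDH9 (-1.29 ± 0.23, 4 of 12) lay near background, and their direction reversed with a normexp background (0.08 and 0.11).

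In total 1550 of 17714 genes passed the threshold with the donor block, 690 higher and 860 lower, and 3369 had an unadjusted p under 0.05. Of the 1550, 593 moved the same way in every donor. The chance share of 0.0977% holds for a gene taken at random. Genes picked by the fit favour agreement, so it is no comparison for the 593. The count was 225 with no donor block and 3493 without the low quality arrays. It was 529 in the first part alone and 961 in the second, 282 with a normexp background and 727 with the series matrix values. Leaving out 1 donor gave 1168 to 1764.

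The p53 list rose as a set after 1 Gy neutron, with 43 of 52 members past the threshold (44 adjusted over the list alone), 0 lower and a median of 1.35 (adjusted p = 1.09e-138; adjusted p = 4.84e-20 with an estimated correlation). B cell markers fell in 19 of 24 members (21 adjusted over the list alone) with a median of -0.86 (adjusted p = 1.35e-37; adjusted p = 1.84e-05 with an estimated correlation, and adjusted p = 0.0943 with an estimated correlation and no donor block). Besides TCL1A they included POU2AF1, a B cell coactivator (-1.06 ± 0.08), the follicle homing receptor CXCR5 (-0.86 ± 0.08) and VPREB3 (-1.28 ± 0.15). NK and cytotoxic markers fell in 23 of 25 members (23 adjusted over the list alone) with a median of -0.67 (adjusted p = 1.07e-32; adjusted p = 6.02e-05 with an estimated correlation). Among them were SH2D1B, an NK adaptor (-1.22 ± 0.14), the granule proteins GZMA (-0.87 ± 0.10) and GNLY (-0.93 ± 0.12), and the chemokine XCL1 (-0.97 ± 0.12). Proliferation genes fell in 10 of 29 members and rose in 1 (11 and 3 adjusted over the list alone), with a median of -0.20 that was 0.13 with a normexp background (adjusted p = 0.000175; adjusted p = 0.0435 with an estimated correlation, and 0.0544 when members shared between lists were also left out). CENPE, a kinetochore motor (-0.67 ± 0.11), and ASPM, a spindle gene (-0.66 ± 0.12), fell, while TYMS, which makes thymidylate, rose by 0.97 ± 0.16. Nucleotide excision and mismatch repair genes rose in 4 of 33 members and fell in 1 (4 and 2 adjusted over the list alone), with DDB2, XPC, the ligase LIG1 (1.1 ± 0.09) and MLH3 (0.43 ± 0.09) higher (adjusted p = 0.00472; adjusted p = 0.0165 with an estimated correlation). Without members shared with other lists, such as DDB2 and XPC of the p53 list, it was not called (adjusted p = 0.407; adjusted p = 0.489 with an estimated correlation). The median of that list was 0.02, and -0.01 with quantile normalization or median scaling.

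For 9 further lists the call after 1 Gy neutron was lost with an estimated correlation. Inflammatory cytokine and NF-kB genes had a median of 0.38 with 4 of 32 higher, BCL2A1, CCL7, CXCL3 and CXCL5 (adjusted p = 2.52e-06; adjusted p = 0.288 with an estimated correlation). MHC class II genes had a median of -0.28 with 6 of 17 lower, such as the peptide loading gene HLA-DMB at -0.58 (adjusted p = 1.56e-05; adjusted p = 0.0963 with an estimated correlation). T cell markers had a median of -0.18, with 4 of 28 lower, such as the costimulator CD27 at -0.54 ± 0.09, and the homing receptor CCR7 higher at 0.40 ± 0.09 (adjusted p = 0.000259; adjusted p = 0.0863 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.29 with 4 of 25 higher, such as ADM at 0.86 (adjusted p = 0.000175; adjusted p = 0.223 with an estimated correlation). Platelet markers had a median of 0.21 with 7 of 21 higher, such as PPBP at 0.57 (adjusted p = 0.000473; adjusted p = 0.16 with an estimated correlation). Plasma cell and immunoglobulin genes had a median of -0.23 with 3 of 11 lower, such as MZB1 at -1.24 ± 0.14 (adjusted p = 0.00289; adjusted p = 0.0963 with an estimated correlation). TNF superfamily genes outside the p53 list had a median of -0.05 but a mean of 0.34 and a call upward (adjusted p = 0.00686; adjusted p = 0.0863 with an estimated correlation, and adjusted p = 0.0344 with an estimated correlation and no donor block). Of 20 genes 5 were higher, such as TNFSF9 at 1.16 ± 0.21 and TNFSF8 at 1.16 ± 0.23, and 1 lower. Their median was 0.04 with a normexp background. Dendritic cell markers had a median of -0.26, and 0.03 with a normexp background, with 4 of 18 lower (adjusted p = 0.0221; adjusted p = 0.123 with an estimated correlation, 0.0727 with no donor block and 0.144 without shared members). Neutrophil markers had a median of 0.12 with 3 of 26 higher, such as FPR2 at 0.76 (adjusted p = 0.0389; adjusted p = 0.288 with an estimated correlation, and adjusted p = 0.276 with no donor block).

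Of the 14 lists that camera called after 1 Gy neutron at the preset correlation, fry also called 14. The other 12 lists were not called after 1 Gy neutron. Heat shock and unfolded protein genes had the lowest adjusted p (0.104, median -0.07, 1 higher and 2 lower of 24). Double-strand break repair genes had 0 higher and 2 lower of 33, such as the helicase BLM (-0.33). Interferon-stimulated genes had 1 higher, TRIM22 (1.38 ± 0.16), and 2 lower of 35, ISG20 and OAS2. Immediate early genes had 3 higher and 1 lower of 23, MYC (-1.27 ± 0.25), with a median of -0.09 and a camera direction upward (adjusted p = 0.891). Ribosomal protein genes had 1 higher of 32, RPS19 (0.68 ± 0.07, adjusted p = 2.5e-12), and 0 lower. Apoptosis genes outside the p53 list had 1 higher and 2 lower of 31, monocyte markers 1 higher and 2 lower of 27, and MHC class I and proteasome genes 0 of 18. Eosinophil and basophil markers had 1 lower of 19, with a median of 0.03 and a mean of -0.01. Oxidative stress genes had 1 lower of 21, oxidative phosphorylation genes 1 lower of 29, and erythroid and globin genes 0 of 18.

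**Figure D1:**
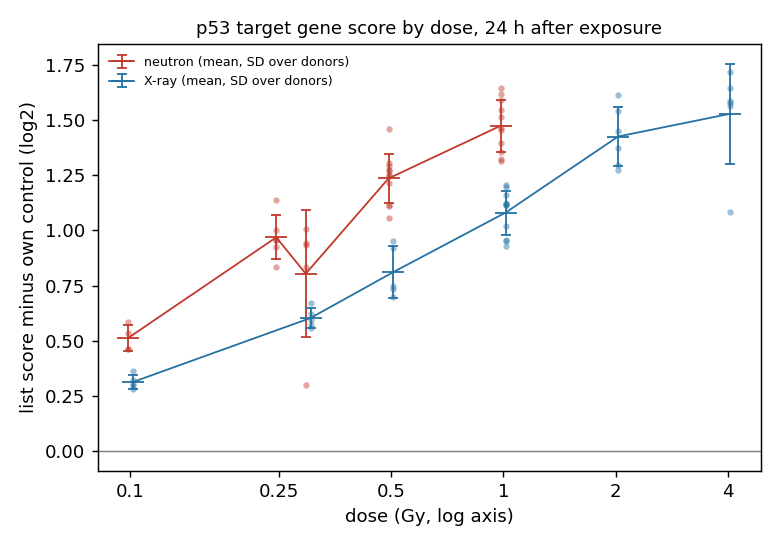
The p53 list score of each irradiated aliquot minus that of its donor's control (vertical axis, log2) is plotted against dose (horizontal axis, Gy, log scale) for neutrons and X-rays, with points for donors and means with SD. The mean at 1 Gy was 1.47 for neutrons and 1.08 for X-rays.

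Next, 1 Gy of X-rays was compared with the control. The same kinds of genes led. EDA2R rose at least 18.5-fold (5.66 ± 0.18, adjusted p = 1.79e-40), FDXR 8.35-fold (3.06 ± 0.11, adjusted p = 3.2e-36), APOBEC3H by 2.99 ± 0.11 and DDB2 5.01-fold (2.32 ± 0.07, adjusted p = 1.74e-40), each in 11 of 11 donors. HRK fell by 1.30 ± 0.17 (adjusted p = 4.27e-08) and TCL1A by 0.89 ± 0.13. All 20 panel genes rose. They included CD70 (2.21 ± 0.11), PHLDA3, an AKT inhibitor (2.08 ± 0.11), and TNFSF4 (2.04 ± 0.18), and the smallest rises were those of SESN1 (1.11) and XPC (1.12 ± 0.12). CDKN1A rose by 1.64 ± 0.24, GADD45A by 1.61 ± 0.06 (adjusted p = 1.97e-36), PCNA, the replication clamp, by 1.47 ± 0.08 and MDM2 by 1.30 ± 0.10. AEN rose by 2.99 ± 0.28, SPATA18 at least 1.23-fold (6 of 11 irradiated arrays well above background) and UNC5B-AS1 at least 1.45-fold (5 of 11).

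Lower after 1 Gy X-ray in every donor were DIPK1B (-0.78 ± 0.11), PACSIN1 (-0.73 ± 0.10), the transcription factor MYC (-1.05 ± 0.25, adjusted p = 0.00894), NEIL1, a base excision glycosylase (-0.58 ± 0.10, adjusted p = 1.77e-05), and FCRL2, a B cell receptor (-0.56 ± 0.15, adjusted p = 0.0235). DOK7 (-1.30 ± 0.20), CORO2B (-0.81 ± 0.20), GALNT14 (-0.66 ± 0.13), SGCE (-0.62 ± 0.18), PRSS57 (-0.54 ± 0.14) and SARS2 (-0.52 ± 0.12) also fell, but their direction reversed with a normexp background. With the donor block 255 genes passed, 164 higher and 91 lower (unadjusted p under 0.05 in 1517). The count was 71 with no donor block, 704 without the low quality arrays, and 123 and 98 in the first and second part alone. With a normexp background it was 59. The control and 1 Gy X-ray aliquots shared a slide in 0 of 11 donors. With slide as a fixed block 79 genes passed, and 11 of 38 results for named genes lost their call. The share that was higher was 64.3%, but 84.7% with a normexp background and 40.5% with the series matrix values. The normexp background moved the median change of all genes by 0.11.

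The p53 list had 36 of 52 members higher after 1 Gy X-ray (39 adjusted over the list alone) and a median of 0.97, or 0.89 with 2 members at their lower bounds (adjusted p = 1e-168; adjusted p = 2.59e-22 with an estimated correlation). B cell markers fell in 8 of 24 members (16 adjusted over the list alone; median -0.39, adjusted p = 2.04e-20, adjusted p = 0.00325 with an estimated correlation). These included VPREB3 (-0.69), POU2AF1 (-0.49) and CXCR5 (-0.42). NK and cytotoxic markers fell in 4 of 25 members (14 adjusted over the list alone; median -0.29, adjusted p = 8.12e-18, adjusted p = 0.00446 with an estimated correlation). The 4 were GZMA (-0.49), XCL1 (-0.54), the adhesion molecule NCAM1 (-0.72) and NCR3 (-0.41). With an estimated correlation and no donor block these B cell and NK values were adjusted p = 0.371 and 0.341. Nucleotide excision and mismatch repair genes rose in 3 of 33 (adjusted p = 0.00348; adjusted p = 0.00922 with an estimated correlation; median 0.01, and -0.03 with median scaling), but without shared members they were not called (adjusted p = 0.578; adjusted p = 0.627 with an estimated correlation). TNF superfamily genes outside the p53 list rose in 4 of 20, such as TNFSF8 at 0.94 and TNFSF9 at 0.81 (adjusted p = 3.09e-05; adjusted p = 0.00446 with an estimated correlation; median 0.04, and -0.08 with the series matrix values).

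At 1 Gy X-ray 11 more lists were called at the preset correlation only. With an estimated correlation, adjusted p = 0.19 for MHC class II genes (median -0.18) and for hypoxia and glycolysis genes (0.18), and adjusted p = 0.322 for inflammatory genes (0.29). It was 0.164 for T cell markers (-0.08), platelet markers (0.21; 1 of 21 higher), dendritic cell markers (-0.17, and 0.20 with a normexp background; 1 of 18 lower) and oxidative phosphorylation genes (-0.08). The same values were adjusted p = 0.228 for proliferation genes (-0.07, and 0.38 with a normexp background), 0.49 for erythroid and globin genes (0.20), 0.291 for plasma cell genes (-0.08; 1 of 11 lower) and 0.496 for ribosomal protein genes (-0.07; 1 of 32 higher). Dendritic cell, erythroid and plasma cell lists were not called with no donor block (adjusted p = 0.0856, 0.2 and 0.355 at the preset correlation). Of the 16 lists that camera called at 1 Gy X-ray at the preset correlation, fry also called 5. The other 10 lists were not called, the lowest adjusted p being 0.152 for heat shock genes.

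The highest dose was 4 Gy of X-rays, with 6 donors of the first part. EDA2R rose at least 42.9-fold (6.86 ± 0.22, adjusted p = 2.99e-40), VWCE 30.8-fold (4.94 ± 0.23), FDXR 23-fold (4.52 ± 0.14, adjusted p = 2.31e-41), CD70 11.1-fold (3.47 ± 0.14) and DDB2 9.42-fold (3.24 ± 0.09, adjusted p = 2.1e-44). VPREB1 was well above background on 0 of 6 irradiated arrays and fell at least 3.56-fold (adjusted p = 1.36e-09). MYC fell 6.45-fold (-2.69 ± 0.31, adjusted p = 1.43e-10), TCL1A 5.17-fold (-2.37 ± 0.16, adjusted p = 3.04e-21) and SH2D1B 4.41-fold (-2.14 ± 0.17, adjusted p = 3.01e-17), each in 6 of 6 donors. KLRF1, an NK receptor, fell by 1.94 ± 0.23, KIR2DS2, an activating receptor, by 1.75 ± 0.25 and CTSW, a protease of killer cells, by 1.74 ± 0.26. NCAM1 (-1.68 ± 0.21), PRSS23 (-1.67 ± 0.20) and FASLG, the Fas ligand (-1.62 ± 0.17, adjusted p = 1.1e-11), fell too. So did the B cell receptor chain CD79B (-1.65 ± 0.24) and HRK (-2.68 ± 0.21). All 20 panel genes rose, GADD45A by 2.75 ± 0.07, CDKN1A by 2.75 ± 0.30, MDM2 by 2.59 ± 0.12, AEN by 2.44 ± 0.35 (5 of 6 donors) and RPS27L, a ribosomal paralog, by 1.00 (5 of 6). E2F7 (19.6-fold, 5 of 11 control arrays well above background) and TMPRSS7, a membrane protease (3.14 ± 0.19), were also among the highest. NTN1, a guidance cue, was higher, but no size is given, since only 2 of 11 control arrays were well above background.

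At 4 Gy X-ray 5526 genes passed with the donor block, 3115 higher and 2411 lower (unadjusted p under 0.05 in 7796), and 2377 of them moved the same way in every donor. The chance share of 3.12% again holds only for a gene taken at random. The count rested on how the fit was made. It was 1548 with no donor block, 4520 without the low quality arrays and 660 with slide as a fixed block. It was 552 with a normexp background and 1356 with the series matrix values. When only the control and 4 Gy arrays were fitted it was 86, in the first part alone 3319 and without 1 donor 2976. The share that was higher was 56.4%, but 38.2% with quantile normalization and 40.3% with median scaling, which moved the median change of all genes by -0.13 and -0.11. In 51 of 1316 called genes with several probes another probe was called the other way. At 2 Gy 602 genes passed (298 higher, 304 lower; unadjusted p under 0.05 in 2491), with 115 with no donor block, 902 without the low quality arrays, 107 with slide as a fixed block and 198 when only those groups were fitted.

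The p53 list rose in 41 of 52 members at 4 Gy X-ray (43 adjusted over the list alone; median 1.22, adjusted p = 3.48e-48, adjusted p = 4.46e-10 with an estimated correlation). NK and cytotoxic markers fell in 23 of 25 (23 adjusted over the list alone; median -1.15, adjusted p = 3.01e-30, adjusted p = 0.000175 with an estimated correlation), GZMB by 1.55, GZMA by 1.48 and GNLY by 1.42. B cell markers fell in 18 of 24 (19 adjusted over the list alone; median -0.72, adjusted p = 1.76e-14, adjusted p = 0.0171 with an estimated correlation). T cell markers fell in 12 of 28 with 1 higher (14 and 1 adjusted over the list alone; median -0.27, adjusted p = 9.18e-06, adjusted p = 0.0417 with an estimated correlation), among them CD27 (-0.74), CD8A (-0.68), the kinase LCK (-0.67) and TCF7 (-0.48). With no donor block the values with an estimated correlation were adjusted p = 0.0996 for NK and 0.513 for both B and T cell markers. Hypoxia and glycolysis genes rose in 16 of 25, such as the mitophagy receptor BNIP3 by 1.31 and the kinase HK2 by 1.25 (median 0.56, adjusted p = 5.75e-06, adjusted p = 0.171 with an estimated correlation). Erythroid genes rose in 8 of 18 (median 0.55, adjusted p = 0.00379, adjusted p = 0.407 with an estimated correlation). Ribosomal protein genes fell in 15 of 32 with RPS19 higher (median -0.21, adjusted p = 8.53e-05, adjusted p = 0.407 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 29 with 1 higher (median -0.21, adjusted p = 0.00272, adjusted p = 0.121 with an estimated correlation). Plasma cell genes fell in 3 of 11 (median -0.26, adjusted p = 0.00539, adjusted p = 0.171 with an estimated correlation) and MHC class II genes in 4 of 17 with 1 higher (median -0.20, adjusted p = 0.0257, adjusted p = 0.407 with an estimated correlation). With no donor block the erythroid, plasma cell and MHC class II lists were not called at the preset correlation (adjusted p = 0.108, 0.066 and 0.335). Of the 10 lists that camera called at 4 Gy X-ray with the donor block, fry also called 10. The other 16 lists were not called. They included platelet markers (adjusted p = 0.0705, and 0.0382 without shared members), apoptosis genes with 4 higher and 11 lower of 31 (adjusted p = 0.0709), double-strand break repair genes with 5 and 7 of 33, repair genes of the excision and mismatch list with 6 and 5 of 33, neutrophil markers with 7 and 1 of 26, and monocyte markers with 5 and 2 of 27, CD14 at 0.76 and CX3CR1 at -1.22.

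The main question between the radiations was whether the same dose of 1 Gy acted differently, by the neutron aliquots against the X-ray aliquots of 11 donors. Many p53 targets were higher after neutrons. GADD45A was 1.8-fold higher (0.85 ± 0.06, adjusted p = 1.65e-19). PCNA was higher by 0.77 ± 0.08 (adjusted p = 4.53e-11) and MDM2 by 0.81 ± 0.10 (adjusted p = 8.78e-09). FDXR was 1.76-fold higher (0.82 ± 0.11, adjusted p = 2.91e-07), APOBEC3H 1.92-fold (0.94 ± 0.11, adjusted p = 5.31e-09) and E2F7 3.15-fold (1.65 ± 0.21, adjusted p = 3.73e-08). TCL1A was 1.9-fold lower (-0.93 ± 0.13, adjusted p = 2.91e-07), as were HRK (-0.99 ± 0.17, adjusted p = 0.000103) and SH2D1B (-0.77 ± 0.14, adjusted p = 0.000161). Each of these went the same way in 11 of 11 donors. Of the 20 panel genes 9 were higher after neutrons, including DDB2 (1.38-fold, 0.47 ± 0.07), CD70 (0.67 ± 0.11), PHLDA3 (0.69 ± 0.11), TNFSF4 (0.98 ± 0.17) and the translesion polymerase POLH (0.48 ± 0.07, 10 of 11 donors). The other 11 did not pass, among them CDKN1A (0.71 ± 0.24, adjusted p = 0.252, 9 of 11 donors), AEN (0.31 ± 0.28, adjusted p = 1), BAX, the pore former (0.29, adjusted p = 1), BBC3 (0.40, adjusted p = 0.0538) and TNFRSF10B (0.22, adjusted p = 0.467).

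Further genes higher after neutrons in every donor were VWCE (2.67-fold, 1.42 ± 0.19), the tachykinin TAC3 (1.12 ± 0.13), the glutaminase GLS2 (0.86 ± 0.14), and the stress cytokine GDF15 (0.84 ± 0.21, adjusted p = 0.026). So were TMPRSS7 (0.82 ± 0.15), UNC5B-AS1 (1.58 ± 0.31, well above background on 12 of 12 neutron and 5 of 11 X-ray arrays) and SPATA18 (1.41 ± 0.20, but -0.06 with a normexp background). Lower in every donor were PRICKLE1 (-1.04 ± 0.18), OSBPL10 (-0.91 ± 0.24, adjusted p = 0.0497), DIPK1B (-0.80 ± 0.11) and the potassium channel KCNG1 (-0.74 ± 0.13). So were the B cell receptor FCRL1 (-0.70 ± 0.15), MZB1 (-0.62 ± 0.14), CPNE5 (-0.60 ± 0.12) and PACSIN1 (-0.59 ± 0.10). In total 112 genes differed with the donor block, 46 higher and 66 lower after neutrons (unadjusted p under 0.05 in 1034), and 61 of the 112 went the same way in every donor. The count was 13 with no donor block, 338 without the low quality arrays, 21 in the first part alone, 47 in the second and 66 without 1 donor. It was 11 with a normexp background, 70 with the series matrix values and 2 with slide as a fixed block. The neutron and X-ray aliquots shared a slide in 0 of 11 donors. The 41.1% that were higher became 52.2% with median scaling, 90.9% with a normexp background and 58.6% with the series matrix values.

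Between the radiations at 1 Gy, 14 of 52 p53 targets were higher after neutrons (30 adjusted over the list alone; median 0.32, adjusted p = 7.96e-70, adjusted p = 4.19e-13 with an estimated correlation). B cell markers were lower in 11 of 24 (18 adjusted over the list alone; median -0.48, adjusted p = 2.45e-39, adjusted p = 1.14e-05 with an estimated correlation), POU2AF1 by -0.57, FCRLA by -0.57 and CXCR5 by -0.44. NK and cytotoxic markers were lower in 5 of 25 (17 adjusted over the list alone; median -0.38, adjusted p = 6.73e-30, adjusted p = 0.000136 with an estimated correlation), GNLY by -0.57, XCL1 by -0.44 and the transcription factor EOMES by -0.42. With no donor block these values with an estimated correlation were adjusted p = 0.234 and 0.132. Neutrophil markers had a median of 0.15 with 0 of 26 past the threshold (adjusted p = 1.62e-05; adjusted p = 0.0252 with an estimated correlation, and 0.667 with no donor block), and proliferation genes a median of -0.15 with 0 of 29 past it (adjusted p = 0.000105; adjusted p = 0.0304 with an estimated correlation). Excision and mismatch repair genes had 2 of 33 higher, DDB2 and LIG1 (adjusted p = 0.0269; adjusted p = 0.0494 with an estimated correlation, 0.234 with no donor block and 0.293 without shared members). Calls lost with an estimated correlation were MHC class II genes (median -0.12, adjusted p = 0.323), plasma cell genes (-0.13, adjusted p = 0.104), T cell markers (-0.09, and 0.01 with the series matrix values, adjusted p = 0.341) and inflammatory genes (0.13, adjusted p = 0.71). With no donor block the T cell and inflammatory lists were not called at the preset correlation (adjusted p = 0.121 and 0.442), and ribosomal protein genes were (adjusted p = 0.0206, against 0.112 with it). Of the 10 lists that camera called between the radiations at 1 Gy with the donor block, fry also called 5. The other 16 lists were not called.

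**Figure D2:**
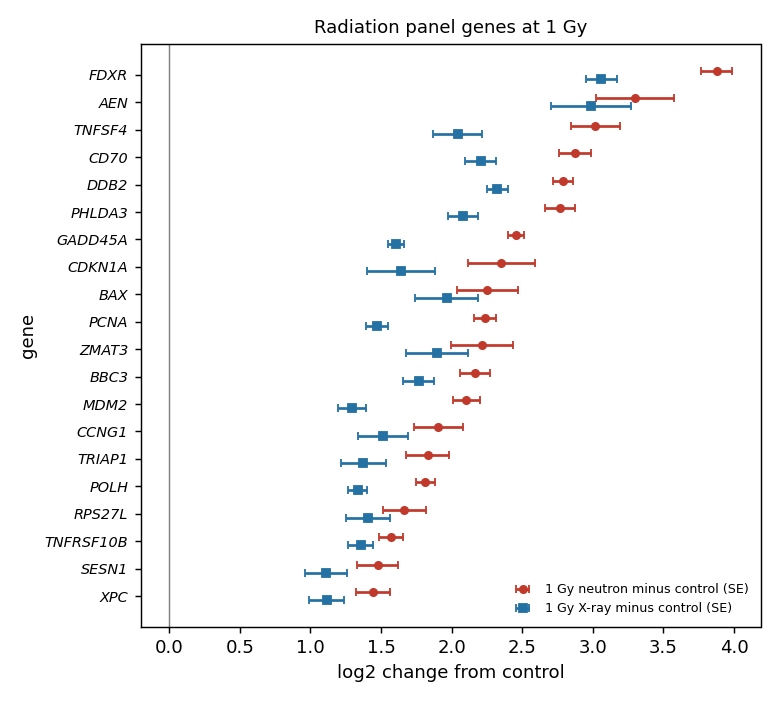
Log2 change from control (horizontal axis) of the 20 panel genes (vertical axis) is shown for 1 Gy neutron and 1 Gy X-ray, with points for the fitted changes and bars for their SE. GADD45A rose by 2.46 after neutrons and 1.61 after X-rays, whereas AEN rose by 3.30 and 2.99.

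The responses to 1 Gy of both radiations overlapped. Of 690 and 164 genes that rose, 160 rose after both (6.39 from independent lists), of 860 and 91 that fell, 86 fell after both (4.42), and 0 moved in opposite directions. Across genes, which are not independent replicates, the changes correlated with r = 0.843 and a covariance of 0.0498. The controls were shared, and in 50 simulations with shared controls and no true change the mean r was 0.462 (highest 0.855), the mean covariance 0.0123 (highest 0.0426) and 0 genes were shared. With 1 Gy neutron fitted in the first part alone and 1 Gy X-ray in the second alone, 73 genes rose after both of 314 and 83 (1.47 from independent lists). Of 215 and 15 that fell, 11 fell after both (0.182), r was 0.506 and the covariance 0.0407. The other way round 88 rose after both of 384 and 99 (2.15), 16 fell of 577 and 24 (0.782), r was 0.47 and the covariance 0.0372. These fits also held fewer arrays and different donors for each exposure, so the lower r cannot be put down to the controls alone.

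The p53 score placed the exposures on 1 scale. After neutrons it exceeded the donor's control by 0.51 ± 0.06 at 0.1 Gy (SD, n = 4), 0.97 ± 0.10 at 0.25 Gy (n = 6), 0.80 ± 0.29 at 0.3 Gy (n = 5), 1.24 ± 0.11 at 0.5 Gy (n = 11) and 1.47 ± 0.12 at 1 Gy (n = 11). After X-rays it exceeded it by 0.31 ± 0.03 at 0.1 Gy (n = 5), 0.60 ± 0.05 at 0.3 Gy (n = 5), 0.81 ± 0.12 at 0.5 Gy (n = 5), 1.08 ± 0.10 at 1 Gy (n = 11), 1.43 ± 0.14 at 2 Gy (n = 6) and 1.53 ± 0.23 at 4 Gy (n = 6). The score was higher in every irradiated aliquot than in its control. At equal dose neutrons exceeded X-rays by 0.39 ± 0.06 at 1 Gy (11 of 11 donors, exact p = 0.000977, adjusted over 4 doses 0.00391), by 0.36 ± 0.04 at 0.5 Gy (5 of 5 donors, exact p = 0.0625), by 0.22 ± 0.27 at 0.3 Gy (5 of 6, exact p = 0.0938) and by 0.19 ± 0.07 at 0.1 Gy (5 of 5, exact p = 0.0625). The X-ray dose that matched on this score was 0.241 ± 0.0169 Gy for 0.1 Gy neutron (SE over 12 donors), 0.666 ± 0.0887 Gy for 0.25 Gy and 1.5 ± 0.0967 Gy for 0.5 Gy. For 0.3 Gy neutron, a group with 1 dim array (signal of 70.89 units), it was 0.512 ± 0.289 Gy, and 0.808 Gy without 1 donor. For 1 Gy neutron it was 3.73 Gy, between 2.89 and 3.88 Gy in fits without 1 donor, and beyond 4 Gy in 3 of 12 such fits. The lowest, 2.89 Gy, left out the donor whose 4 Gy X-ray array had a signal of 81.76 units. Without the low quality arrays the dose was 3.09 Gy. Within the first part 1 Gy neutron gave 1.53 ± 0.11 (n = 6, on the same slide as the control) and within the second 1.40 ± 0.09 (n = 5, on different slides). The difference of -0.13 between the parts had an exact p of 0.0628.

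**Figure D3:**
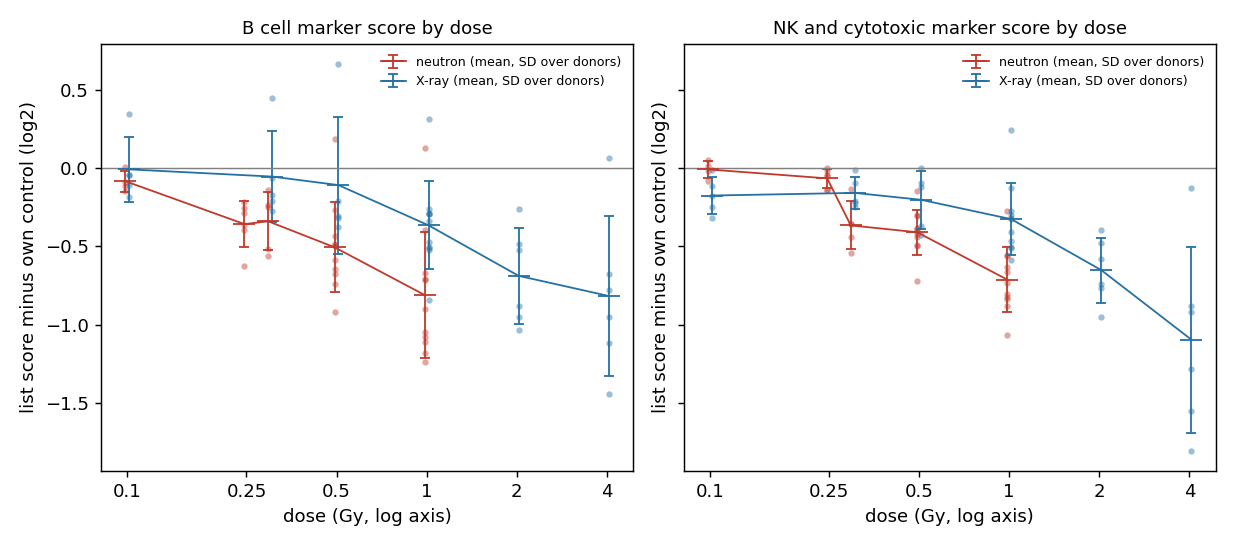
B cell and NK scores minus the donor's control (vertical axes, log2) are plotted against dose (horizontal axis, Gy, log scale), with points for donors and means with SD. At 1 Gy the B cell score was lower by 0.81 after neutrons and 0.37 after X-rays.

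B cell and NK scores were lower at 1 Gy and above, and their means were also lower at 0.25, 0.3 and 0.5 Gy neutron. In single donors the B cell change lay between -0.144 and 0.009 at 0.1 Gy neutron (n = 4). At 0.3 Gy neutron it lay between -0.559 and -0.14 (n = 5). The B cell score changed by -0.36 ± 0.15 at 0.25 Gy neutron (SD, n = 6), -0.51 ± 0.29 at 0.5 Gy (10 of 11 donors lower) and -0.81 ± 0.41 at 1 Gy (10 of 11, exact p = 0.00195), and by -0.37 ± 0.28 at 1 Gy X-ray (10 of 11, exact p = 0.00586), -0.69 ± 0.31 at 2 Gy and -0.82 ± 0.51 at 4 Gy (5 of 6 lower). At 0.1, 0.3 and 0.5 Gy X-ray it changed by -0.01 ± 0.21, -0.05 ± 0.29 and -0.11 ± 0.44 (n = 5 each). Those means rest on 1 donor. Without it they were -0.10 ± 0.07, -0.18 ± 0.09 and -0.30 ± 0.07, lower in 4 of 4 donors at each dose. That donor was left out after these values had been seen and was the only donor to rise at these doses. The 4 of 4 therefore follows from leaving it out and is no test. It was kept in the other B cell values given here. The NK score changed by -0.71 ± 0.21 at 1 Gy neutron (11 of 11, exact p = 0.000977) and by -0.33 ± 0.23 at 1 Gy X-ray (10 of 11, exact p = 0.00293), -0.65 ± 0.21 at 2 Gy and -1.1 ± 0.59 at 4 Gy (6 of 6). Below 1 Gy it changed by -0.01 ± 0.06, -0.07 ± 0.06, -0.37 ± 0.15 and -0.41 ± 0.14 at 0.1, 0.25, 0.3 and 0.5 Gy neutron. At 0.1, 0.3 and 0.5 Gy X-ray it changed by -0.18 ± 0.12, -0.16 ± 0.10 and -0.20 ± 0.19, lower in 5, 5 and 4 of 5 donors. At 0.1 Gy the NK score was higher after neutrons than after X-rays by 0.18 ± 0.12 (4 of 5 donors, exact p = 0.125). At 1 Gy the difference between the radiations was -0.45 ± 0.18 for B cells and -0.39 ± 0.18 for NK cells, negative in 11 of 11 donors (exact p = 0.000977 for B cells, adjusted over 18 comparisons 0.0117), and -0.07 ± 0.11 for T cells (9 of 11, exact p = 0.0557). The neutrophil score rose by 0.12 ± 0.19 after 1 Gy neutron (exact p = 0.0479, adjusted over 18 comparisons 0.422), which did not hold up.

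Lower doses asked how early genes responded. At 0.1 Gy neutron 23 genes rose and 0 fell (unadjusted p under 0.05 in 239), 13 of them in the p53 list. EDA2R rose by at least 5.8-fold (4.02 ± 0.24), APOBEC3H by 1.84 ± 0.15, FDXR by 1.81 ± 0.15, CD70 by 1.36 ± 0.15, DDB2 by 1.33 ± 0.10 and GADD45A by 0.84 ± 0.08, each in 4 of 4 donors. At 0.1 Gy X-ray 8 genes rose and 0 fell (575), all in 5 of 5 donors: EDA2R (at least 3.48-fold), APOBEC3H (0.89 ± 0.14), FDXR (0.88 ± 0.14), CD70 (0.87 ± 0.14), DDB2 (0.81 ± 0.09), the noncoding PVT1 (0.48 ± 0.09), GADD45A (0.44 ± 0.07) and LOC100128670 (0.43). PVT1, LOC100128670 and the phosphatase PHPT1 were named after their values had been seen. Between the radiations at 0.1 Gy 5 genes differed (282), all higher after neutrons in 5 of 5 donors: APOBEC3H and FDXR by 0.94 ± 0.16, DDB2 by 0.52, PHPT1 by 0.44 and GADD45A by 0.40. Without a donor block the 3 counts were 12, 3 and 0 (25 at an unadjusted p under 0.05), and without the low quality arrays 45, 20 and 9. With a normexp background they were 5, 0 and 0, and when only the compared groups were fitted 1, 0 and 0. Leaving out 1 donor gave 17 to 31, 6 to 11 and 2 to 8, the last with 8, 3 and, for each of 4 donors, 2.

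At 0.25 Gy neutron 87 genes passed (84 higher, 3 lower), at 0.3 Gy 238 (139 and 99) and at 0.5 Gy 629 (298 and 331). At 0.3 Gy X-ray 35 passed, all higher, and at 0.5 Gy X-ray 95 (90 and 5). FDXR rose by 1.81, 2.81, 3.09, 3.31 and 3.88 over the 5 neutron doses from 0.1 to 1 Gy and by 0.88, 1.99, 2.39, 3.06, 3.53 and 4.52 over the 6 X-ray doses from 0.1 to 4 Gy. DDB2 rose by 1.33, 2.05, 2.22, 2.41 and 2.79, and by 0.81, 1.63, 1.93, 2.32, 2.62 and 3.24. All 20 panel genes passed from 0.25 Gy neutron and from 0.5 Gy X-ray upward. Between neutrons and X-rays 15 genes differed at 0.3 Gy (13 higher, 2 lower), such as FDXR by 1.11 ± 0.15 and E2F7 by 1.74. At 0.5 Gy 18 genes differed (18 higher, 0 lower; unadjusted p under 0.05 in 1502), such as GADD45A by 0.75 ± 0.07 (adjusted p = 2.12e-11) and POLH by 0.60. The count at 0.3 Gy neutron lay between 89 and 1173 in fits without 1 donor: it was 1173, 551 and 89 without each of 3 donors. With no donor block the counts were 43 at 0.25 Gy, 67 at 0.3 Gy and 93 at 0.5 Gy neutron, 20 and 49 at 0.3 and 0.5 Gy X-ray, and 4 and 7 between the radiations. With a normexp background 20 genes passed at 0.3 Gy neutron, and 0 and 1 between the radiations at 0.3 and 0.5 Gy. When only the compared groups were fitted these 3 counts were 0, 0 and 0. Without 1 donor the count at 0.5 Gy neutron was 403. Without the low quality arrays the counts were 160, 164 and 2073 for the neutron doses, 84 and 291 for the X-ray doses, and 21 and 90 between the radiations. The share higher at 0.3 Gy neutron, 58.4%, was 35.2% with quantile normalization, 42.6% with median scaling and 31.2% with the series matrix values, and at 0.5 Gy X-ray 94.7% became 60.9%, 40.9% and 47.8%. In the same order the median change of all genes moved by -0.12, -0.11 and -0.12 at 0.3 Gy neutron. At 0.5 Gy X-ray it moved by -0.16 with median scaling and -0.13 with the series matrix values.

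Straight dose slopes in the second part asked whether genes rose faster per Gy after neutrons. GADD45A rose by 2.19 ± 0.14 per Gy of neutrons and 1.22 ± 0.15 per Gy of X-rays on the log2 scale, a difference of 0.97 ± 0.15 (adjusted p = 9.2e-05). E2F7 differed by 2.21 ± 0.32 per Gy (adjusted p = 2.9e-05) and PCNA by 0.94 ± 0.15. TCL1A fell by 1.68 and 0.59 per Gy, a difference of -1.09 ± 0.13 (adjusted p = 6.3e-07), KCNG1 differed by -0.87 ± 0.10 (adjusted p = 9.6e-08) and HRK by -1.20 ± 0.16. The slopes of FDXR differed by 1.20 (adjusted p = 0.061), of DDB2 by 0.61 (adjusted p = 0.24) and of AEN by 0.29 (adjusted p = 0.85), none past the threshold. Compared dose by dose at 0.1, 0.3 and 0.5 Gy, however, FDXR was called higher after neutrons (0.94, 1.11 and 0.91), as was DDB2 (0.52, 0.59 and 0.49). How well a straight line follows the doses was not tested. With the donor block 1684 genes had a neutron slope (656 up, 1028 down), 108 an X-ray slope (92 and 16) and 293 a different slope (84 and 209). The counts were 270, 42 and 6 with no donor block and 3246, 195 and 843 without the low quality arrays. Leaving out 1 donor gave 987 to 3196, 69 to 162 and 85 to 738. The neutron slope count was 3196, 1023 and 987 without each of 3 donors. The different slope count was 738, 528, 179, 156, 124 and 85 without each of the 6 donors. The X-ray slope count was 69 without 1 donor and 162 without another. Of the neutron slopes 39% were upward, 52.1% with median scaling and 50.7% with the series matrix values. Of the different slopes 28.7% were upward, and 41.3%, 63.5%, 58.3% and 60% with quantile normalization, median scaling, a normexp background and the series matrix values.

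Doses in a ratio of 1 to 4 were compared in the fit of all arrays. Each pair held a dose that only the first part used, so only donors of that part were paired. The groups of 0.5 and 1 Gy neutron and of 1 Gy X-ray also held arrays of the second part. Counts with the first part alone are given further below, and the last was far lower there. Between 0.25 Gy neutron and 1 Gy X-ray limma called 0 genes, with 588 at an unadjusted p under 0.05, and 2 in a fit without 1 donor. Between 0.5 Gy neutron and 2 Gy X-ray it called 1, VASH1, an angiogenesis inhibitor (-0.49 ± 0.09, adjusted p = 0.00807, 6 of 6 donors lower after neutrons), with 1386 at an unadjusted p under 0.05. VASH1 was named after its value had been seen, and limma called 0 genes in fits without each of 3 donors (1461, 1599 and 421 at an unadjusted p under 0.05) and 3 and 2 in fits without each of 2 others. The p53 score differed by -0.14 and -0.13, lower after neutrons in 6 of 6 donors in both. Between 1 Gy neutron and 4 Gy X-ray 2926 genes differed, 1049 higher and 1877 lower after neutrons (6350), with FDXR lower by -0.65 ± 0.14 and DDB2 by -0.45 ± 0.09 (5 of 6 donors), while the mean p53 score differed by 0.01 ± 0.26. That mean hides a direction: the score was lower after neutrons in 5 of 6 donors, and by -0.095 ± 0.086 on average without the donor of the dim 4 Gy array. Of the 20 panel genes 1 was higher and 6 were lower. NK and cytotoxic markers were higher after neutrons in 15 of 25 members (median 0.44, adjusted p = 5.72e-11, adjusted p = 0.162 with an estimated correlation). That count of 2926 was 202 with no donor block, 1705 without the low quality arrays, 0 with slide as a fixed block (2473 at an unadjusted p under 0.05 in limma), 0 when only those groups were fitted (1129), and 502 and 4520 without each of 2 donors. The 35.9% higher after neutrons became 55.2% with quantile normalization, 55.3% with median scaling and 22.2% with a normexp background.

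Whether the 2 parts responded differently was tested over the 3 exposures that both parts used. The limma test called 0 genes with 919 at an unadjusted p under 0.05, and 2 in fits without each of 2 donors. In data simulated with independent noise this test recovered 46.5% of changed genes.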

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

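The tests of whether all lymphocytes fell alike, of slide as a fixed block, alone and in the fits without 1 donor, and of the fits without the low quality arrays were chosen only after the result was seen, and the rule for reading the spread of values on the dim array was altered after its result was seen.

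In groups of 4 to 10 samples, 32 groups of values were tested for 1 sample far from the others, 6 had one, and chance alone would give 1.6. At 0.3 Gy neutron 1 array had a p53 score of 0.302 over its control, the others 0.835 to 1.006, and its signal of 70.89 units was also far below the others' 788 to 1158. At 4 Gy X-ray 1 array had a p53 score of 1.08 over its control, the others 1.57 to 1.72, and a signal of 81.76 units, the others 678 to 995. The B cell score minus control was 0.344 in 1 donor at 0.1 Gy X-ray, the others -0.187 to -0.043, and 0.667 in 1 donor at 0.5 Gy X-ray, the others -0.377 to -0.210. Both came from the same donor and share 1 control array, so they are 1 observation rather than 2 independent ones. Of 1158 probes without a gene name, which no comparison used, 6 passed the threshold at 1 Gy neutron, 3 at 1 Gy X-ray, 362 at 4 Gy X-ray and 1 between the radiations at 1 Gy.

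The first pattern was the count of 5526 genes at 4 Gy X-ray against 602 at 2 Gy. Low array quality is argued against: without those arrays the counts were 4520 and 902, a ratio of 5.01. Chance in 1 donor is argued against too, since the lowest ratio in a fit without 1 donor was 3.83 (2976 against 778). The slide shared by a donor's X-ray arrays is argued against as the whole cause, though not as a cause of part of the 5526. With slide as a fixed block the counts were 660 and 107, and the lowest ratio in a fit that also left out 1 donor or the low quality arrays was 2.59 (171 against 66). On the same slides 4 Gy against 1 Gy called 876 genes and 2 Gy against 1 Gy called 4. The bound set in advance was met the other way, since 876 is 26.4% of the 3319 against control there and under 50, but it was wrong: 1 Gy already holds part of the 4 Gy response, which lowers that share with or without a slide effect. Array position cannot be told apart from X-ray dose here. In every donor of the first part the 1, 2 and 4 Gy X-ray arrays sat at slide positions 1, 2 and 3. Neither the slide block nor the comparisons on the same slides separate position from dose, so position was not tested and stays open. A larger response at the higher dose, which the design names, may also be the reason. The direction as well as the size depends on the fit: when only the compared groups were fitted 4 Gy called 86 genes and 2 Gy called 198, but 478 and 119 without the low quality arrays.

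The second pattern was that B cell and NK markers were lower after 1 Gy neutron than after 1 Gy X-ray, the B cell score by 0.445. The slide layout of the first part is argued against by a difference of -0.455 in the second part, negative in 5 of 5 donors, beside -0.437 in the first. Scaling of the arrays is argued against by -0.429 under the scaling with the smaller effect. An equal fall of B and T cell markers is argued against because the B cell score was lower by more than the T cell score. The difference was -0.372 (SE 0.069, 10 of 11 donors). A lower share of all lymphocytes alike is argued against only if marker RNA per cell stayed the same, which was not measured. A lower number of B and NK cells and a lower expression per cell may each give this pattern, and no test separated them.

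The third pattern was the low p53 score on the dim array at 0.3 Gy neutron. An unirradiated sample under this label is argued against, since the score of 0.302 over its control was 2.99 SDs of the control scores (SD 0.101). Low signal of that array could not be decided: the signal was 70.89 units, but the spread of its log2 values, 2.77, was not the smallest of its group, the lowest of the others being 2.74 with an SD of 0.055 among them. The other array flagged for low signal, at 4 Gy X-ray with 81.76 units, also had the low p53 score of its group, 1.08. The array of 315.5 units at 2 Gy X-ray was not flagged for either value. A low signal that compresses dim genes may therefore still be the reason, and no biological explanation was tested, since the design gives none for 1 array of a group.

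Labels were exchanged within donors (doses for slopes, donors between the parts for the test between parts) to ask how often chance gives as many genes, the real labels counted as 1 of the splits. Only the real labels gave as many in the results that follow, and 1 split is the lowest that such a test can give. No adjustment was made over the results tested, so chance is argued against in each alone and not excluded. These were 1 of 32 splits at 0.25 Gy neutron (87, the highest other 38) and 1 of 100 at 0.5 Gy neutron (629, 188), at 1 Gy neutron (1550, 792) and at 1 Gy X-ray (255, 109). They were 1 of 32 at 2 Gy X-ray (602, 268) and at 4 Gy X-ray (5526, 4851). Between the radiations they were 1 of 32 at 0.3 Gy (15, 5) and 1 of 100 at 1 Gy (112, 37). For the neutron slope (1684, 454) and the X-ray slope (108, 0) they were 1 of 100, and for the slope difference 1 of 32 (293, 54). At 4 Gy X-ray exchanged labels still called up to 4851 genes, so the splits do not tie the size of that count to the dose. The splits were too few for a share under 0.05 at 0.1 Gy neutron (1 of 8 splits, 23 genes, highest other 7) and, with 16 splits, at 0.3 Gy neutron (238, 64), at 0.1, 0.3 and 0.5 Gy X-ray (8, 35 and 95, highest others 3, 16 and 59) and between the radiations at 0.1 and 0.5 Gy (5 and 18, highest others 1 and 4). Exchanged labels gave as many or more for 2 pairs of doses. Of 32 splits 3 gave at least the 1 gene of 0.5 Gy neutron against 2 Gy X-ray (highest other 2). In the same way 4 of 32 gave at least the 2926 genes of 1 against 4 Gy (highest other 5197). With 0 genes called every split gives as many, so the splits say nothing for 0.25 Gy neutron against 1 Gy X-ray (32 of 32 splits, highest other 0) or for the test between the parts (100 of 100, highest other 41).

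Without the low quality arrays only the real labels gave as many as 3493 genes in 1 of 100 splits at 1 Gy neutron (highest other 2267). The splits were too few for a share under 0.05 at 4 Gy X-ray (8 splits, 4520 genes, highest other 1591), at 2 Gy X-ray (8, 902, 168) and between 1 Gy neutron and 4 Gy X-ray (4, 1705, 70).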

How the results depend on the processing

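Every alternative below was fixed before the data were examined, except leaving out the low quality arrays and fitting slide as a fixed block, which were chosen only after the results had been seen. Depth limited the dim genes: between 48.6% and 88% of the probes were well above background on an array, and the normexp background, which treats dim spots differently, changed more counts than the scalings did.

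The p53 score results kept their direction in every alternative run. The score at 1 Gy neutron minus control was 1.47 (1.007 with a normexp background), at 1 Gy X-ray 1.08 (0.709 with it), and the difference between the radiations 0.393 (0.298 with it). In the second part alone they were 1.40, 1.04 and 0.359, with an exact p of 0.0625 each, the smallest that 5 donors can give. The X-ray dose that matched 1 Gy neutron, 3.73 Gy, lay between 3.09 Gy without the low quality arrays and 3.94 Gy with no donor block in the alternatives that kept all donors and gave a value. Without the donor of the dim 4 Gy array it was as low as 2.89 Gy, and it lay beyond 4 Gy in 3 of 12 fits without 1 donor. It also had no value, because the score exceeded that at 4 Gy, with quantile normalization, median scaling, the series matrix values, the first part alone and the median of the list's genes.

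Of 1045 alternative values for genes named at 1 Gy neutron, 1024 kept direction and side of the threshold, as did 943 of 1020 at 1 Gy X-ray, 1004 of 1033 at 4 Gy X-ray and 950 of 1103 between the radiations at 1 Gy. In 9 the direction reversed, all with a normexp background, and the cause was not tested. They were ZMAT4 (0.076) and PCDH9 (0.105) at 1 Gy neutron, DOK7 (0.065), CORO2B (0.358), GALNT14 (0.262), SGCE (0.211), PRSS57 (0.123) and SARS2 (0.065) at 1 Gy X-ray, and SPATA18 (-0.057) between the radiations.

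Counts of genes past the threshold moved more. The cause was not tested for any of the counts given here, beyond the fewer arrays that a fit of 1 part or of only the compared groups holds. The values given are those over 1.5 times away from the count with all arrays and the donor block.

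With no donor block the counts were 12, 43, 67, 93 and 225 at 0.1, 0.25, 0.3, 0.5 and 1 Gy neutron and 3, 20, 49, 71, 115 and 1548 at 0.1, 0.3, 0.5, 1, 2 and 4 Gy X-ray. Between the radiations they were 0, 4, 7 and 13 at 0.1, 0.3, 0.5 and 1 Gy, then 0 between 0.5 Gy neutron and 2 Gy X-ray and 202 between 1 Gy neutron and 4 Gy X-ray, and 270, 42 and 6 for the neutron slope, the X-ray slope and their difference. The limma fits behind the 2 zero counts had 25 and 530 genes at an unadjusted p under 0.05.

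With a normexp background and in the same order they were 5, 23, 20, 158 and 282 for neutrons, 0, 8, 25, 59, 96 and 552 for X-rays, 0, 0, 1 and 11 between the radiations, 0 and 9 for the pairs of doses, and 255, 28 and 12 for the slopes. The 4 zero counts had 147, 36, 268 and 568 genes at an unadjusted p under 0.05.

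With the series matrix values, which cover fewer genes, they were 12, 52, 324 and 727 at 0.1, 0.25, 0.5 and 1 Gy neutron, 5, 18 and 1356 at 0.1, 0.3 and 4 Gy X-ray, 1, 5, 36 and 70 between the radiations, 0 (649 at an unadjusted p under 0.05) and 387 for the pairs of doses, and 613, 66 and 110 for the slopes.

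Without the low quality arrays they were 45, 160, 2073 and 3493 at 0.1, 0.25, 0.5 and 1 Gy neutron, 20, 84, 291 and 704 at 0.1, 0.3, 0.5 and 1 Gy X-ray, and 9, 90 and 338 between the radiations at 0.1, 0.5 and 1 Gy. They were 1 between 0.25 Gy neutron and 1 Gy X-ray, 0 between 0.5 Gy neutron and 2 Gy X-ray (596 at an unadjusted p under 0.05), 1705 between 1 Gy neutron and 4 Gy X-ray, and 3246, 195 and 843 for the slopes.

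With slide as a fixed block they were 13 and 96 at 0.1 and 0.3 Gy neutron, 16, 79, 107 and 660 at 0.1, 1, 2 and 4 Gy X-ray, 4, 2 and 2 between the radiations at 0.3, 0.5 and 1 Gy, 0 and 0 for the pairs of 0.5 and 2 Gy and of 1 and 4 Gy (596 and 2473 at an unadjusted p under 0.05), and 53 and 3 for the X-ray slope and the slope difference.

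When only the arrays of the compared groups were fitted they were 1, 41 and 0 at 0.1, 0.25 and 0.3 Gy neutron, 0, 4, 11, 198 and 86 at 0.1, 0.3, 0.5, 2 and 4 Gy X-ray, 0, 0 and 0 between the radiations at 0.1, 0.3 and 0.5 Gy, and 0 and 0 for the last 2 pairs of doses. The 7 zero counts had 385, 1120, 565, 399, 1266, 1227 and 1129 genes at an unadjusted p under 0.05.

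In the first part alone they were 201 and 529 at 0.5 and 1 Gy neutron, 123, 383 and 3319 at 1, 2 and 4 Gy X-ray, 21 between the radiations at 1 Gy, and 1, 0 and 280 for the 3 pairs of doses (730 at an unadjusted p under 0.05 for the zero). In the second part alone they were 138, 407 and 961 at 0.3, 0.5 and 1 Gy neutron, 98 at 1 Gy X-ray and 47 between the radiations at 1 Gy. With both parts up to 1 Gy the slopes gave 2704, 391 and 566.

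With median scaling they were 5 at 0.1 Gy X-ray, 2 and 37 between the radiations at 0.1 and 0.5 Gy, 0 between 0.5 Gy neutron and 2 Gy X-ray (1355 at an unadjusted p under 0.05), and 1047 and 137 for the neutron slope and the slope difference. With quantile normalization they were 33 between the radiations at 0.5 Gy and 2 for the test between the parts, which gave 1 with slide as a random block. With donor as a random block they were 419 at 0.5 Gy neutron, 50 between the radiations at 1 Gy and 184 for the slope difference. With the mean of all kept probes 5 genes differed between 0.5 Gy neutron and 2 Gy X-ray. No count moved by over 1.5 times with no filter or a stricter filter on dim probes.

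Fits without 1 donor gave 17 to 31, 67 to 98, 89 to 1173, 403 to 815 and 1168 to 1764 genes at the 5 neutron doses, and 6 to 11, 30 to 46, 76 to 115, 187 to 303, 411 to 778 and 2976 to 6323 at the 6 X-ray doses. Between the radiations they gave 2 to 8, 11 to 21, 12 to 27 and 66 to 135, for the pairs of doses 0 to 2, 0 to 3 and 502 to 4520, for the slopes 987 to 3196, 69 to 162 and 85 to 738, and for the test between the parts 0 to 2. The p53 score ranged from 1.46 to 1.49 at 1 Gy neutron, from 1.068 to 1.096 at 1 Gy X-ray and from 0.386 to 0.406 between them, and the matching dose from 2.89 to 3.88 Gy in the 9 fits that gave one.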

Other observations

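The tests of the NK list against the p53 list and of the B cell list at 0.25 and 0.3 Gy or in the first part alone, and the fit of JUN without the low quality arrays, were chosen only after the result was seen, and the test of a common dose ratio on the B cell list at 0.5 Gy was written before it.

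A hypothesis was that 1 ratio of X-ray to neutron dose describes the p53, B cell and NK lists. On the p53 list 0.5 Gy neutron matched 1.5 ± 0.0967 Gy of X-rays (SE over 12 donors), on the B cell list 1.52 ± 0.126 Gy and on the NK list 1.24 ± 0.169 Gy. The B cell dose exceeded the p53 dose by 0.023 ± 0.136 Gy at 0.5 Gy, by 0.156 ± 0.135 Gy at 0.25 Gy and by 0.587 ± 0.389 Gy at 0.3 Gy neutron. In the first part alone the direction turned, with -0.063 ± 0.153 Gy at 0.5 Gy and -0.079 ± 0.057 Gy at 0.25 Gy. All lay within 2 SE of 0, so a common ratio may hold for these 2 lists. For the NK list it is argued against at 0.25 Gy alone: 0.25 Gy neutron matched 0.0591 ± 0.0385 Gy there and 0.666 ± 0.0887 Gy on the p53 list, a difference of -0.607 ± 0.083 Gy. The 0.0591 Gy was read across donors, since 0.25 Gy neutron was in the first part and X-rays under 1 Gy in the second. In the first part alone the difference was -0.672 ± 0.109 Gy. The dose of 0.3 Gy neutron was only in the second part, and its group had 1 dim array. There the NK list matched 0.955 ± 0.292 Gy and the p53 list 0.512 ± 0.289 Gy, a difference the other way of 0.443 ± 0.523 Gy. At 0.5 Gy it was -0.263 ± 0.255 Gy, and -0.554 ± 0.346 Gy in the first part alone. So a common ratio may hold at those 2 doses within 2 SE. At 1 Gy neutron the NK list matched 2.10 ± 0.233 Gy, between 2.02 and 2.29 Gy in fits without 1 donor. The p53 list matched 3.73 Gy, from 2.89 Gy to beyond 4 Gy in such fits, so the 2 ranges did not overlap. The p53 dose had no SE, so a common ratio of these lists was not tested there. The B cell list exceeded its change at 4 Gy and gave no dose.

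At 0.1 Gy, inflammatory cytokine and NF-kB genes were lower after neutrons than after X-rays by a median of -0.62 (adjusted p = 0.0452 with an estimated correlation) and immediate early genes by -0.30 (adjusted p = 0.0273 with an estimated correlation), with 0 genes of either list past the threshold. Camera at the preset correlation called 16 lists at 0.1 Gy, of which 4 held with an estimated correlation and 1 with fry. So fry did not call both of these lists. At 1 Gy the median difference of the inflammatory list was 0.13. At 0.3 Gy the transcription factor JUN was lower after neutrons by -0.77 ± 0.14 (adjusted p = 0.00143, 6 of 6 donors). Without the donor of the dim 0.3 Gy array it was lower by -0.64 ± 0.15 but no longer called (adjusted p = 0.0837), and without all low quality arrays by -0.67 ± 0.15 (adjusted p = 0.0205). The call was also lost with a normexp background (-0.60 ± 0.15, adjusted p = 0.922) and when only the compared groups were fitted (-0.77 ± 0.20, adjusted p = 0.791).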
